A study of Rattus norvegicus with 4 samples.

How the data were processed

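Gene expression was measured on 4 Agilent rat 2-colour arrays, 1 for each of 1, 3, 7 and 14 days of reperfusion after 4 h of ischemia of the gracilis muscle. Per the labels, total RNA was amplified and labelled by in vitro transcription, the injured muscle with Cy5 and the sham-operated control with Cy3. The orientation was the same on all 4 arrays, and the series' design text gives 1 experimental and 1 control replicate per condition.

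The deposited files are the scanner software's output for each array. Per the file headers the images were extracted with Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 9.5.3. The deposited intensity of a spot is its mean pixel brightness, given with the median brightness of its local background, neither of them normalized. The deposited LogRatio is the log10 of red over green after background subtraction, spatial detrending and linear and LOWESS dye normalization, per the file headers. The deposited p-value of each spot comes from the software's own error model. The deposited value table gives log2 ratios. Set against each array's LogRatio times log2(10) over the 40972 probes with 1 spot, it differed by at most 0.005, with r = 1 and a median of 0 in every column, so its scale, centring and direction (injured over sham) were settled. Probe positions in the results follow the rn4 coordinates of the files.

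Ratios were computed from the mean and background intensities with R 4.3.3 and limma 3.58.1. The background was corrected with normexp and an offset of 50, and each array was normalized by loess, with control spots and outlier spots given no weight. Spots of 1 probe were averaged, and the probe with the highest mean brightness stood for its gene. A gene was used on a day if it was well above background in at least 1 channel. Saturated spots were kept. Where 1 channel was saturated or not well above background, the fold is a bound and written as at least N-fold, with the dim channel set to the lowest signal among probes well above background where that was higher. Levels of single channels came from quantile normalization of the mean brightness after loess. On day 14, 2 genes had probes at least 2-fold from sham in opposite directions, on day 3 there was 1, and on days 1 and 7 there was none. Probes of 1 gene could still differ widely in size, and unless stated a value is that of the brightest probe.

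Names came from a table of rat genes of the assembly GRCr8, used for names only. Accessions matched 10938 probes, current symbols 1645 and older symbols 460. Names from the design's time with the suffix for predicted genes matched 3537 more, and symbols in the description column 125. The last 2 ways were added after the data were seen. Among 150 probes with an accession that also carried such a name, 140 (93.3%) gave the same symbol. The other 24307 probes kept the name in the file.

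With 1 array per day there is no test for a day. Genes at least 2-fold from sham were counted, as were genes whose ratio differed at least 2-fold between consecutive days. For 34 gene lists the median was set among 10000 random lists matched on brightness. The mean over the 4 arrays was tested against 0 with limma and Benjamini-Hochberg adjustment at 0.05, over genes measured on every array. Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, for each day, the 8 highest and 8 lowest genes with a symbol, the 3 members of each list farthest in the direction of its median, miR-21 targets at least 2-fold from sham on any day, a fixed set of markers (among them Pax7, Myod1, Myog, Myh3, Myh8, Myh4, Ckm, S100a8, Cd68, Ccl2, Il6, Spp1, Col1a1, Tgfb1, Mki67, Hmox1, Pdcd4, Spry1, Reck, Timp3), and the 10 genes with the smallest adjusted p in each direction. No probe was matched to the names Pax7 or Myh8. A probe described as similar to PAX7 kept the name in the file. Other genes in the text, such as list members that went against their median, were chosen after their values were seen.

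The steps were tested on simulated data. In arrays made from the real sham signals with a dye trend and 200 genes changed, the count for day 1 recovered 99% of the genes set to a log2 change of 1.5 and 100% of those set to 3, over 16772 genes, with 0 unchanged genes called. For days 3, 7 and 14 the shares were 99%, 100% and 99% at 1.5, over 14679, 12485 and 16466 genes. The injured signal was here the sham signal with added noise. The changed genes were bright and went up and down in equal number. These shares therefore do not cover an array such as the real day 1, with 285 genes higher and 1127 lower. Of 200 lists with no change 4% fell outside the range, and a list shifted by 1 reached percentile 100. The unchanged lists were themselves drawn at random with independent noise, so a small share outside was fixed in advance. It does not cover real lists, whose genes can vary together. The test of the mean recovered 69% of genes set to 1.5 and 86% of those set to 3 among 20540, with 8 unchanged genes called. Its simulated arrays were independent, with no deviation of a shared sham and no constant dye effect, so the 8 calls cover neither.

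Alternatives were the software's own processed signals, the deposited value table, no background correction, an offset of 0, median centring in place of loess, no filter on dim probes, both channels well above background, the median of a gene's probes, a threshold of 3-fold, the software's p-value under 0.01, saturated spots left out, the injured channel against the mean of the 4 sham channels, direct comparison of injured channels, random lists without matching, and leaving out each time point. A search for miR-21 seed sites in 3' untranslated regions had been planned and was left out, since no rat transcript sequences were at hand. Spike-in and other control spots were left out of every comparison.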

Results

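RNA from the gracilis, a strap-like adductor muscle of the thigh, of male Sprague-Dawley rats was measured after 4 h of ischemia followed by 1, 3, 7 or 14 days of reperfusion. Each of the 4 time points was a single 2-colour Agilent rat array, on which the injured muscle (Cy5) was read against a sham-operated muscle (Cy3). There was 1 injured and 1 sham sample per array and no dye swap, so no value below has a replicate, the number of arrays limits the precision, and a dye effect of a single probe cannot be separated from a difference between the muscles. Each array carried 41372 gene spots for 41012 probes. Between 64.4% and 68.7% of the probes were well above background in the injured channel, and 47.3%, 41.1%, 34.7% and 46.4% in the sham channel on days 1, 3, 7 and 14. Genes measured in at least 1 channel numbered 22954, 24475, 23503 and 23757. Among 40 probes printed 10 times on each array, the log2 ratio had an SD of 0.06, 0.07, 0.07 and 0.04, which is spot noise within an array and not the spread between animals.

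Values are log2 ratios of injured to sham, named as higher or lower when they differed at least 2-fold, which is a rule of size and not a test. No unoperated muscle was measured, so the ratios do not show how either muscle differed from undisturbed muscle. A gene list, fixed beforehand, is called above or below its range when its median lay in the outer 2.5% on either side of 10000 random lists of the same size and brightness on that array. Genes of 1 list can vary together, which random lists do not copy, so this position describes the array and is not a test. The sham channels gave a yardstick for counts between single channels: across genes, which are not independent replicates, they correlated between arrays at r from 0.967 to 0.994, and 145, 940, 107, 662, 253 and 692 genes differed at least 2-fold between the sham channels of days 1 and 3, 1 and 7, 1 and 14, 3 and 7, 3 and 14, and 7 and 14. The labels do not say whether the same sham RNA was used on every array. The arrays of days 1, 3 and 7 were scanned in 1 session and that of day 14 in another, so that day 14 and its session cannot be told apart.

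The first comparison asked how the muscle differed from sham after 1 day of reperfusion. Transcripts of the contractile apparatus were far scarcer than in sham muscle. All 14 measured genes of adult fast fibres were lower, with a median of -3.12 (8.68-fold lower). Its 3 lowest members were Tnnc2, fast troponin C, at least 10.4-fold lower because its sham spot was saturated, the myosin light chain Myl1 at -3.35, and the calcium buffer parvalbumin, Pvalb, at -3.30. Of 12 slow fibre genes 10 were lower (median -3.93), led by Tnnc1, slow and cardiac troponin C, which was 31.9-fold lower, Csrp3 at -4.18 and the light chain Myl3 at -4.13. Of 18 genes for excitation-contraction coupling and fibre structure 14 were lower (median -3.40), with nebulin, Neb, 21.5-fold lower and triadin, Trdn, at -4.30. The other lowest genes of the array were Ckmt2, mitochondrial creatine kinase of muscle (30.4-fold lower), Ampd1, muscle AMP deaminase (28.6-fold), Car3, carbonic anhydrase 3 (25.2-fold), Asb2 (at -4.64), Cox8b, a muscle subunit of cytochrome oxidase (22.1-fold), and Fhl1 (21.7-fold). By their probes nearest sham Ampd1 was at -0.066, Cox8b at -0.732 and Trdn at -1.648. Cytosolic creatine kinase, Ckm, was at -3.23 and the fast myosin Myh4 at -2.88. Against the mean of the 4 sham channels Tnnc2 was at -2.51 and Myh4 at -2.07.

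Genes of muscle energy metabolism and of muscle formation were lower as well on day 1. Fatty acid oxidation had a median of -1.34, with 16 of 22 genes lower, led by Cpt1b, the carnitine transferase of muscle mitochondria, at -4.31, and Fabp3 at -2.42. The other probe of Cpt1b was at -0.387. Glycolysis and glycogen had a median of -1.31, with 12 of 20 lower, among them Ldhb at -3.78, Eno3 at -3.11 (-2.32 against the mean of the 4 sham channels) and Pfkm at -3.06. Oxidative phosphorylation (-0.97, 16 of 33 lower) and the tricarboxylic acid cycle (-0.71, 7 of 18 lower) also lay below their ranges, but both were above 0, at 0.32 and 0.42, when the array was only centred on its median. Of 18 genes of regenerating and embryonic muscle 13 were lower (median -2.42), with the slow troponin Tnni1 16.2-fold, Mustn1 14.4-fold and the myogenic factor Myog 13.4-fold lower, and embryonic myosin, Myh3, at -3.08. The myogenic factor Myod1 was at -0.18. Below their ranges were also the lists for the neuromuscular junction (-0.92), for atrophy and ubiquitin (-0.70), with the ubiquitin ligase Trim63 at -3.44, and for smooth muscle and pericytes (-0.70). Extracellular matrix had a median of -0.63, with the fibrillar collagens Col1a1 at -2.54, Col3a1 at -2.42 and Col1a2 at -1.48, the first 2 at -1.06 and -1.73 against the mean of the 4 sham channels. This median too was above 0, at 0.46, under median centring.

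Lists of innate immune cells and their signals lay above their ranges on day 1. The neutrophil list lay at 0.82, with 4 of 16 genes higher, and its leading members were the paired calcium-binding proteins of neutrophil cytosol, S100a9 (6.13-fold higher) and S100a8 (5.67-fold), and the granulocyte factor Cebpe at 1.39. Itgam, the integrin CD11b of neutrophils and monocytes, was 6.74-fold higher. The monocyte and macrophage list lay at 0.43, and the complement component C1qa was 2.01-fold lower, so its members differed in direction. Cytokines and chemokines lay at 0.64, with 9 of 27 genes higher, among them the interferon-induced chemokine Cxcl10 (5.45-fold), the monocyte attractant Ccl2 at 2.08, saturated in the injured channel (1.43 against the mean of the 4 sham channels), and Ccl7 at 1.57. Interferon response genes lay at 0.62, with Ifit1 4.95-fold higher, Ifit2 at 1.68 and Oas1a at 1.37. By their probes nearest sham Ifit1 was at 0.335 and Ifit2 at 0.436. Il6 was at 0.54, Tgfb1 at 0.55, Cd68 at 0.59 and Hmox1, heme oxygenase 1, at 1.00. Also among the 8 highest were C3h15orf48 (5.76-fold) and the arginine-degrading enzyme Arg1 (4.55-fold). Smaller medians above their ranges were those of the immediate early (0.46), apoptosis (0.27), lymphocyte (0.20), endothelium (0.17) and protease (0.14) lists.

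In all, 285 genes were at least 2-fold higher and 1127 at least 2-fold lower than sham on day 1, of which 173 and 596 had a gene symbol, and 17 and 344 passed 4-fold. The counts and their balance depended on the processing: the deposited ratios gave 2771 higher and 1966 lower, and median centring gave 5003 and 433.

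**Figure D1:**
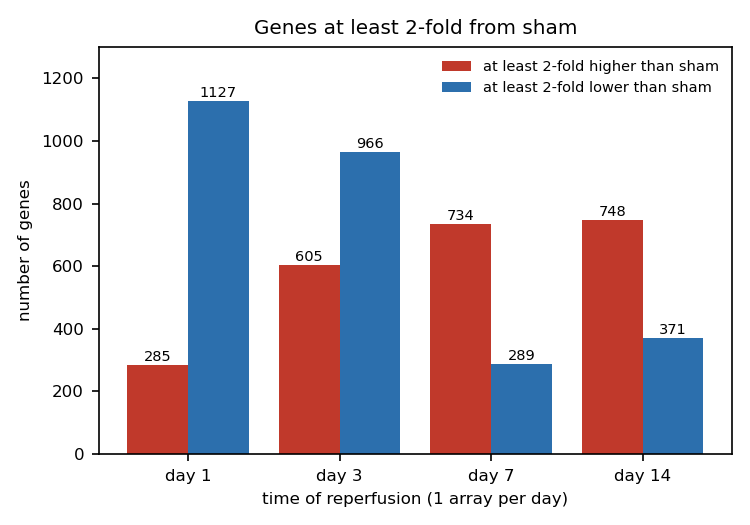
Number of genes at least 2-fold higher (red) or lower (blue) than sham on each day (y axis, genes; x axis, day of reperfusion; 1 array per day, so the bars have no error). Lower genes outnumbered higher ones on days 1 and 3, with 1127 against 285 and 966 against 605, and higher genes outnumbered lower ones on days 7 and 14, with 734 against 289 and 748 against 371.

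After 3 days the same muscle genes were scarce, and genes of cell division and of the matrix were higher than in sham. All 14 fast fibre genes were lower (median -4.14), led by Actn3, fast alpha-actinin (37.4-fold lower), Pvalb at -5.18 and Tnnc2, at least 28.7-fold lower. Slow fibre genes lay at -4.28 (10 of 12 lower), with Csrp3 41.3-fold and Tnnc1 at -4.98, and coupling and structure genes at -3.26, with Trdn 49.4-fold and Neb 38.5-fold lower. Ampd1 was 84.1-fold and Ckmt2 49.8-fold lower, followed by Cox8b (39.3-fold) and Car3 (37.5-fold). Ampd1 and Cox8b are given by their brightest probes, and on day 1 another probe of either gene was within 2-fold of sham. Myh4 was at -3.62 and Ckm at -4.29. Against the mean of the 4 sham channels Actn3 was at -4.55, Car3 at -4.44, Tnnc2 at -4.22 and Myh4 at -2.89. Glycolysis lay at -1.46, fatty acid oxidation at -1.10, oxidative phosphorylation at -1.02 and the tricarboxylic acid cycle at -0.62, with Cpt1b at -4.32 and Pygm, muscle glycogen phosphorylase, at -3.60. The last of these medians was 0.29 under median centring.

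Of 38 cell cycle genes 19 were higher on day 3 and none lower (median 1.00). The mitotic regulator Cdkn3 was at 2.01, cyclin B1, Ccnb1, at 1.89, Plk1 at 1.88 and the proliferation marker Mki67 at 1.82. Extracellular matrix lay at 1.01, with 16 of 32 genes higher and none lower, led by Col5a2 at 1.85, Col1a1 at 1.80 and the collagen cross-linking enzyme Loxl2 at 1.79. Complement lay at 0.44, with Cfd at 1.57, C1s at 1.52 and C1r at 1.45. Regenerating muscle genes had a median of -0.36, below the range, with members on both sides: Mustn1 36.7-fold lower and Actc1 at -3.83, but Myod1 at 1.95. That median was 0.34 under median centring. Interferon response genes lay at -0.48 (0.27 under median centring), with Ifit1 at -1.69, mast cell genes at -0.56, heat shock and oxidative stress genes at -0.42 and neutrophil genes at -0.15, with S100a8 at -0.20. Atrophy and ubiquitin lay at -0.96, Trim63 among them at -4.82, and the neuromuscular junction at -0.25. Under median centring the heat shock, neutrophil, atrophy and neuromuscular junction medians were all above 0. Immediate early genes lay at 0.22. Ccl2 was at -0.14, Il6 at -0.09 and Cd68 at 0.57.

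The highest genes of day 3 were Gal, the neuropeptide galanin (9.22-fold), the phosphatase Ptprf (7.55-fold), the protease inhibitor Cst6 (6.79-fold), the secreted Wnt modulator Sfrp2 (5.83-fold), Sned1 (5.13-fold), the B cell attractant Cxcl13 (4.76-fold), Sytl2 (4.67-fold) and Gdnf, a growth factor for motor neurons (4.37-fold). In all, 605 genes were higher and 966 lower, 26 and 281 of them by 4-fold. The deposited ratios gave 3785 and 1827, and median centring 4198 and 395.

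By day 7 most fast fibre genes lay near sham, slow fibre genes did not, and the regenerating muscle, interferon, complement and extracellular matrix lists lay above their ranges. Embryonic myosin, Myh3, was at least 33.8-fold higher, with a saturated injured spot, and the fetal growth factor Igf2 was 24.5-fold higher. The regenerating muscle list lay at 0.88, with 9 of 18 genes higher and 2 lower, among the higher ones the embryonic acetylcholine receptor subunit Chrng (8.41-fold). The neuromuscular junction list lay at 0.45, with Chrng and the subunit Chrna1 at 2.62. Myog was at -0.02, and Myod1 at 1.01 against a sham level of 8.72 that was the lowest of the 4 arrays, but at -0.54 against the mean of the 4 sham channels. The fast fibre list was inside its range at -0.18, with 11 of 14 genes within 2-fold, Myh4 at -0.78 and Ckm at -0.48 or above (saturated in the injured channel), while Pvalb was 10.4-fold lower. Slow fibre genes lay at -1.31, with 8 of 12 lower, led by the light chains Myl3 (17.5-fold) and Myl2 (14.6-fold) and the slow myosin Myh7 (15.9-fold). Ppp1r1a, Tuba8, the cardiac myosin Myh6 and the stretch-responsive Ankrd2 were 15.1-fold, 15.1-fold, 14.1-fold and 12.5-fold lower.

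Interferon response genes had a median of 1.55 on day 7, with 16 of 22 higher and none lower, led by Ifit2 at 3.42, the regulator Irf7 at 3.12 and Rsad2 at 3.00. Ifi27l2b, of an interferon-inducible family, was 12.1-fold higher by its brighter probe, but at 2.27 against the mean of the 4 sham channels. Complement lay at 1.80 (9 of 15 higher), with C4a at 2.83 and C6 at 2.59, and the extracellular matrix at 1.32 (18 of 31 higher), with Col1a1 at 3.27 (saturated in the injured channel, 2.66 against the mean of the 4 sham channels), Col6a1 at 2.95 and Col1a2 at 2.77. Cxcl10 was 29.4-fold, the lipid desaturase Scd 29.4-fold, Cxcl13 21.2-fold, C1qa 11.8-fold and the collagen Col16a1 11.3-fold higher. Monocyte and macrophage genes lay at 0.49, with 9 of 23 higher, such as C1qa and the Fc receptor Fcgr3a at 3.07, and 4 lower, such as the scavenger receptor Cd163 at -1.95. Lymphocyte genes lay at 0.39, above the range, with 6 of 18 higher and 1 lower, and at 0.19, inside it, with dim spots set to their bound. Cd3g, of the T cell receptor complex, was at 2.89. Immediate early (0.43), smooth muscle (0.46), endothelium (0.37) and oxidative phosphorylation (0.24) lists lay above their ranges, the last at -0.05 against the mean of the 4 sham channels.

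Below their ranges on day 7 were the cell cycle list (-0.39, no member past 2-fold, Mki67 at -0.49), which was 0.02 under median centring, heat shock and oxidative stress (-0.58), atrophy (-0.45), fatty acid oxidation (-0.35) and glycolysis (-0.26), each of the last 4 above 0 under median centring. S100a8 was at -1.67, Spp1, osteopontin, at -1.31, Ccl2 at -1.04 (-0.73, within 2-fold, against the mean of the 4 sham channels) and Hmox1 at -0.82. In all, 734 genes were higher and 289 lower, 171 and 39 of them by 4-fold. The deposited ratios gave 4097 and 1911, median centring 2722 and 78, and the injured channel against the mean of the 4 sham channels gave 718 lower.

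On day 14 fast fibre genes were above sham and slow fibre genes below it. The fast list lay at 1.23, with 9 of 14 genes higher and none lower, led by the myosin Myh2 (9.36-fold), Pvalb at 2.37 and the troponin Tnnt3 at 1.65, and Myh4 was at 1.53. Against the mean of the 4 sham channels Pvalb was at 1.65, Tnnt3 at 1.04 and Myh4 at 0.44. The slow list lay at -1.19, with 7 of 12 lower, led by Myl2 (10.7-fold), the troponin Tnnt1 at -2.75 and Myh7, at least 6.32-fold lower with a saturated sham spot. Glycolysis (0.58, with Pgam2 at 2.30), oxidative phosphorylation (0.49), the tricarboxylic acid cycle (0.34), coupling and structure (0.32) and fatty acid oxidation (0.30) all lay above their ranges. Myh3 was still 20.4-fold and Igf2 7.99-fold higher, and the regenerating list lay at 0.31, with Myog at -1.22 and Myod1 at 0.12.

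The matrix, complement, interferon and lymphocyte lists lay above their ranges on day 14. The matrix list lay at 1.21, with 18 of 32 genes higher and none lower, Col1a1 at least 13.8-fold higher (2.66 on the log2 scale against the mean of the 4 sham channels), the matricellular protein Postn at 3.24 and Col3a1 at 2.60 (saturated in the injured channel). Complement lay at 1.91, with 9 of 15 higher and 2 lower, Cfb among the higher ones at 3.22, and interferon response genes at 1.47, with 13 of 22 higher, Irf7 among them at 2.60. Lymphocyte genes lay at 0.62, with 6 of 17 higher and 1 lower, Cd3g at 3.44 and Cd3d at 2.65, and the T cell chemokine Ccl5 at 3.58. Cxcl13 (16.1-fold), the cartilage matrix protein Cilp (14.7-fold), the protease Klk1 (at 3.59), Atp1b4 (11.4-fold) and Ifi27l2b (10.9-fold) were also among the 8 highest. The other probe of Ifi27l2b was at -0.059. The smooth muscle list lay above its range (0.36). The mast cell (0.37) and adipocyte (0.33) lists did so too, but not with dim spots set to their bound (0.25 and 0.21).

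Inflammation genes lay on both sides of sham on day 14, and the cytokine and chemokine list was inside its range at -0.06, with 7 genes higher and 6 lower. Spp1 was 21.3-fold, S100a8 7.09-fold, the matrix protease Mmp10 8.71-fold and the reductase Akr1b8 8.54-fold lower, Ccl2 was at -2.56, Hmox1 at -1.95 and the macrophage receptor Cd163 at -2.50. The injured level of Mmp10 was at percentile 0.05 of the genes measured, so its fold is limited by the floor of the channel. The monocyte and macrophage list lay at -0.38 with 6 genes higher and 8 lower, proteases and their inhibitors at -0.27 with 5 higher and 8 lower, and neutrophil genes at -0.22. The first 2 of these lay at 0.12 and 0.003 under median centring. Cell cycle genes lay at -0.60 (Cdk1 at -1.38), heat shock and oxidative stress at -0.67 (Mt1, metallothionein, at -2.57) and atrophy at -0.23, the last 2 above 0 under median centring. The class II gene RT1-Bb of the major histocompatibility complex was 9.38-fold lower by its brighter probe, but higher by 2.09 on the log2 scale by its other probe. In all, 748 genes were higher and 371 lower, 155 and 48 of them by 4-fold. The deposited ratios gave 4101 and 1534 and median centring 2884 and 98.

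**Figure D2:**
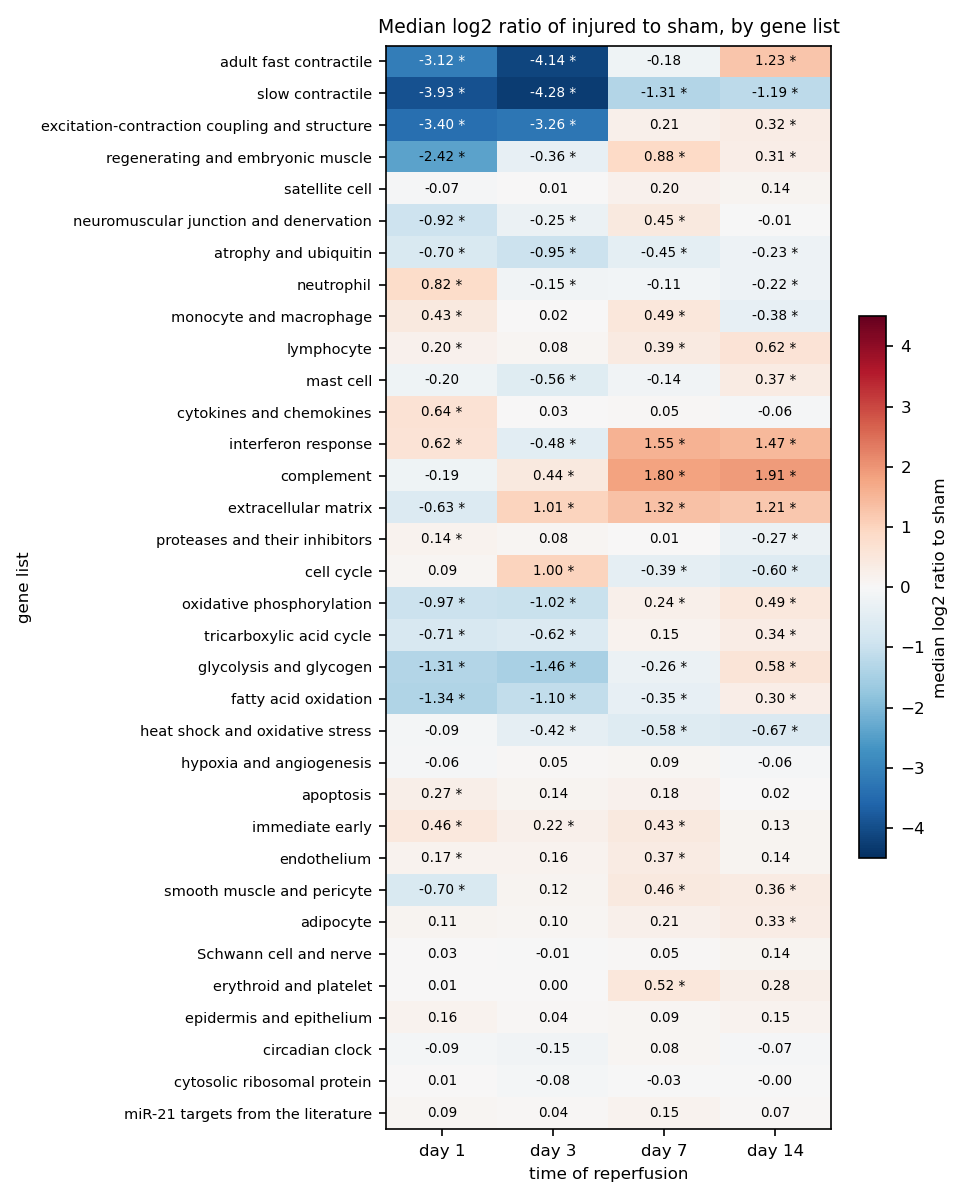
Median log2 ratio of injured to sham (colour and printed value) for each of the 34 gene lists (rows) on days 1, 3, 7 and 14 (columns), 1 array per day; an asterisk marks a median outside the range of the random lists. The fast contractile list goes from -3.12 and -4.14 on days 1 and 3 to 1.23 on day 14, while the slow list is -1.19 on day 14.

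The series also implies a comparison of consecutive time points, made here on the ratios to sham. From day 1 to day 3 the ratio was at least 2-fold higher for 689 genes and lower for 369 of 22292. Among those higher on day 3 were Col1a1 (by 4.34), Col3a1 (by at least 4.03, saturated on day 3) and Sfrp2 (by 3.08), and among those lower Ifit1 (by 3.99), S100a9 (by 3.01) and the monocyte chemokine receptor Ccr2 (by 2.69), genes picked here and in the next lines after their values were seen. Against the mean of the 4 sham channels Col1a1 was at -1.06 on day 1 and 2.05 on day 3, a smaller step. From day 3 to day 7 the numbers were 1081 higher and 497 lower of 22344: Ampd1 was higher by 7.20 by its brighter probe, Trdn by 6.28 and Myh3, saturated on day 7, by at least 5.32, while Gal was lower by 3.46, Cdk1 by 2.59 and Mki67 by 2.31. From day 7 to day 14 the numbers were 396 and 270 of 21821, with Pvalb higher by 5.75 and Myh2 by 2.65, and RT1-Bb lower by 5.69 by its brighter probe, while its other probe went from 0.51 to 2.09, Gdnf lower by 3.40 and Spp1 by 3.10. Compared directly between the injured channels, without the sham channels, the counts were 787 and 604, then 1177 and 1224, then 1079 and 490, in all 1391, 2401 and 1569 genes, where the sham channels of the same arrays differed for 145, 662 and 692.

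Across genes, which are not independent replicates, the ratios of days 1 and 3 correlated at r = 0.687 and those of days 7 and 14 at r = 0.665. The correlation was 0.350 for days 3 and 7, 0.127 for days 3 and 14, 0.113 for days 1 and 7, and -0.094 for days 1 and 14. Lower on both days 1 and 3 were 755 genes, where independent lists would share 48.3, and higher on both days 7 and 14 were 412, where independent lists would share 24.9. Of the genes measured on days 1 and 14, 161 were lower on day 1 and higher on day 14. If the arrays shared 1 sham RNA, unchanged muscles would by simulation have shared 21.5 lower and 21.6 higher genes in these 2 cases. Part of the excess may therefore come from the shared control. The simulated correlation of about 0.5 (0.502 for days 1 and 3) was fixed by giving the sham and each muscle the same spread. That spread came from the sham channels of days 1 and 14, which agreed best (SD of the difference 0.211, against 0.474 for days 1 and 7). A wider spread would raise the simulated overlaps, so they set no upper limit on the part of the shared control. The covariance was 0.235 for days 1 and 3 and 0.160 for days 7 and 14, against simulated values of 0.023 and 0.024, which a wider spread would raise as well.

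**Figure D3:**
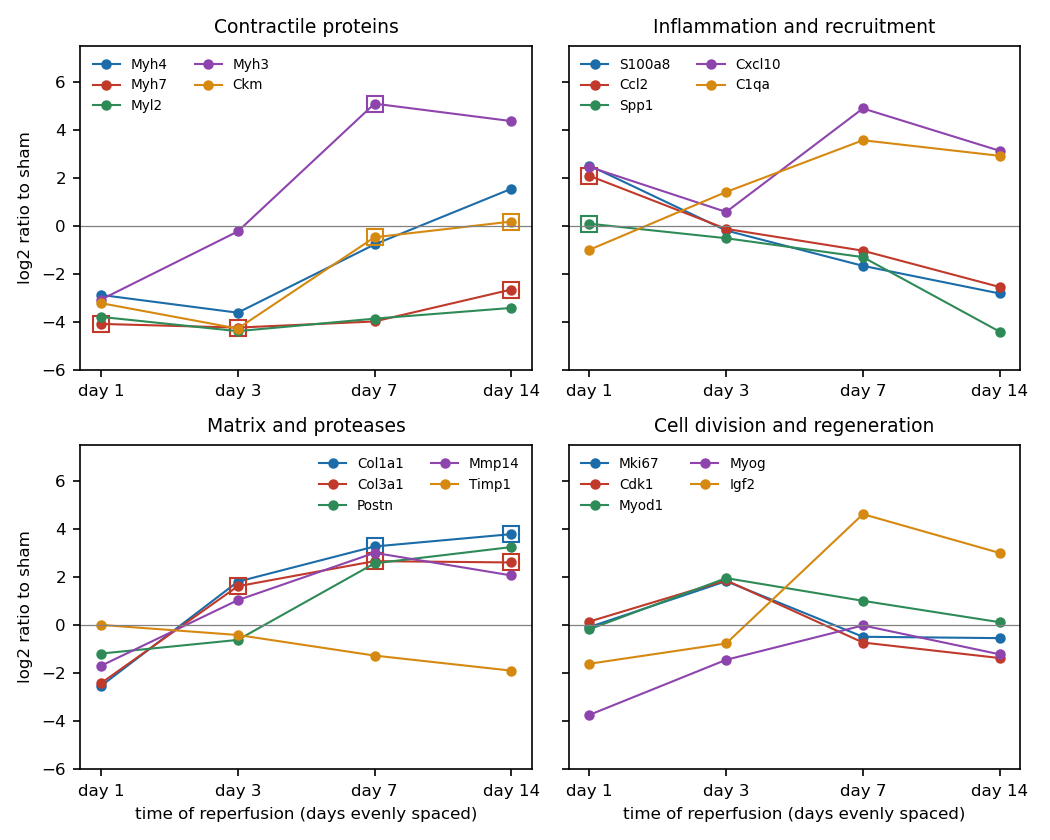
Log2 ratio to sham (y axis) of 20 genes from the fixed lists, chosen after their values were seen, on days 1, 3, 7 and 14 (x axis, evenly spaced), 1 array per point; open squares mark a spot saturated in 1 channel. Myh3 goes from -3.08 on day 1 to 5.08 on day 7, Myh7, with a saturated sham spot on days 1, 3 and 14, stays at -2.66 or below, and S100a8 goes from 5.67-fold higher on day 1 to 7.09-fold lower on day 14.

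The test fitted was whether a gene's mean ratio over the 4 arrays differed from sham (limma, Benjamini-Hochberg adjusted p under 0.05, n = 4 time points standing in for replicates). It treats the 4 ratios as independent. If 1 sham RNA served all arrays, which the labels do not say, its own deviation would shift all 4 alike. The p-values would then be too small. A constant dye effect of a probe could pass this test as well, since the injured muscle was in Cy5 on every array. A trend over time, or early against late days, was not tested. Of 20540 genes 5 rose and 32 fell, all 37 with the same sign on every day. The deposited ratios gave 600 and 178 and median centring 8398 and 132, so the balance of rises and falls depended on the processing. The genes with the smallest adjusted p were Ankrd2, a stretch-responsive protein of slow fibres (mean -3.74 ± 0.13 SE, adjusted p = 0.015), and the small GTPase Rrad (-2.72 ± 0.09, adjusted p = 0.015). Mmp10, natriuretic peptide B (Nppb) and Myl2 fell (means -3.10, -2.40 and -3.87, each adjusted p = 0.017), as did the deaminase Cda and the adhesion protein Chl1 (-1.52 and -1.45, both adjusted p = 0.0285), and the pericyte proteoglycan Cspg4, Myh6 and the synaptic scaffold Homer2 (-1.20, -3.82 and -1.37, each adjusted p = 0.0369). The injured level of Mmp10 was at percentile 32.8, 0.02, 0.09 and 0.05 of measured genes on days 1, 3, 7 and 14. On the last 3 of these days it was near the floor and its ratio could fall little further. Of the genes that rose, Tmsb15b2, a thymosin beta, had a symbol (1.13 ± 0.08, adjusted p = 0.0369), with a sham spot near background on every day, and with both channels required above background no gene rose. Next in order, and not passing, were the cyclin Ccnl1 (0.74, adjusted p = 0.0562), Cd83 (0.75, adjusted p = 0.0572), the sialoglycoprotein Spn (1.92, adjusted p = 0.0625), Twist1 (0.92, adjusted p = 0.0633), neuropeptide Y, Npy (1.54, adjusted p = 0.0663), Slc16a6 (0.81, adjusted p = 0.0708) and xanthine dehydrogenase, Xdh (1.46, adjusted p = 0.0742). At least 2-fold on every day were 5 genes higher, of which Cxcl13, Spn, Npy and Xdh had symbols, and 52 lower. Of the slow fibre list 2 of 12 genes fell over all genes and 7 adjusted over the list alone, of the atrophy list 1 and 9, and of heat shock and oxidative stress 0 and 8, beside 1 that rose adjusted over the list alone. Leaving out day 14, the only array of its scan session, left 0 genes higher and 8 lower, and leaving out day 1, 3 or 7 left 0 in either direction.

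The title of the series names target genes of the microRNA miR-21, which represses the transcripts it binds. Of 45 published targets on the array, 37, 39, 40 and 42 were measured on the 4 days, and the list's median was 0.09, 0.04, 0.15 and 0.07, at percentiles 93.2, 66.5, 96.4 and 69.4 of the random lists and so inside the range each day. Members at least 2-fold from sham were few and lay on both sides. The muscle tropomyosin Tpm1 was at -2.69 on day 1 and -3.40 on day 3 (-2.01 and -2.79 against the mean of the 4 sham channels) and the mitochondrial enzyme Acat1 at -1.79 and -1.42, while the kinase Map2k3 was at -1.22 (0.17 under median centring) and -1.14. The 4 probes of Tpm1 ran from -3.04 to 0.28 on day 1. Lrrfip1 was at 1.25 on day 1, the GTPase Rhob at 1.09 on day 3 (0.96 against that mean) and 1.73 on day 7, and Anp32a at -2.10 and Tgfbi at -1.29 on day 14. Of the much-studied targets, these stayed within 2-fold on every day: Pdcd4 lay between -0.51 and -0.06, Spry1 between -0.13 and 0.81, Reck between -0.16 and 0.81, and Timp3 between -0.16 and 0.30. No member passed the test of the mean, either over all genes or adjusted over the list alone. With genes named by accession and symbol alone, 30 targets were measured on day 1 and their median was 0.27, above the range of -0.15 to 0.13.

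Among the remaining lists, satellite cell genes (-0.07, 0.01, 0.20 and 0.14 on days 1, 3, 7 and 14), hypoxia and angiogenesis (-0.06, 0.05, 0.09 and -0.06), Schwann cells and nerve (0.03, -0.01, 0.05 and 0.14), epidermis (0.16, 0.04, 0.09 and 0.15), the circadian clock (-0.09, -0.15, 0.08 and -0.07) and cytosolic ribosomal proteins (0.01, -0.08, -0.03 and 0.00) stayed inside their ranges each day. A probe described as similar to PAX7, the satellite cell factor, which no naming step matched, was at -0.02, 0.04, 0.41 and 0.26. The hypoxia list held members on both sides, such as Bnip3 at -1.99 on day 1 and Angpt2 at 1.48 on day 7.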

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

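The tests of the 3 patterns below were all chosen after the patterns were seen.

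For 16 gene lists the median lay outside the range of random lists on opposite sides on different days. These differences between time points were not tested, since each is between 1 array and another. From the lowest to the highest day the median differed by 5.38 for adult fast contractile genes (day 3 to day 14), 3.72 for excitation-contraction coupling (day 1 to 14), 3.30 for regenerating muscle (day 1 to 7), 2.04 for glycolysis (day 3 to 14), 2.02 for interferon response (day 3 to 7), 1.94 for extracellular matrix (day 1 to 7), 1.64 for fatty acid oxidation (day 1 to 14) and 1.51 for oxidative phosphorylation (day 3 to 14). It differed by 1.37 for the neuromuscular junction (day 1 to 7), 1.15 for smooth muscle (day 1 to 7), 1.04 for the tricarboxylic acid cycle (day 1 to 14) and 0.93 for mast cells (day 3 to 14, when their median was inside the range at 0.25 with dim spots set to their bound). In the other direction in time it differed by 1.60 for the cell cycle (highest on day 3, lowest on day 14), 1.04 for neutrophils and 0.42 for proteases (both day 1 and day 14), and 0.88 for monocytes and macrophages (day 7 and day 14). Under median centring in place of loess the only low medians of 5 of these lists turned above 0: interferon response (0.27 on day 3), extracellular matrix (0.46 on day 1), monocytes and macrophages (0.12 on day 14), proteases (0.003 on day 14) and the tricarboxylic acid cycle (0.42 and 0.29 on days 1 and 3).

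The control spots of the array's spike-in RNA, which no comparison uses, had a median red over green signal of 6.85 on day 14, against 2.60, 3.58 and 3.58 on days 1, 3 and 7. Gene spots had 1.19 on day 14 and 1.58, 1.62 and 1.65 on the other days.

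Of 86 measured genes of the neutrophil, macrophage, cytokine and protease lists, 24 were at least 2-fold lower than sham on day 14 and 17 at least 2-fold higher, and the 24, picked for being low, had a median of -1.98 (Spp1, S100a8, Ccl2, Ctsl and Timp1 among them). A constant dye or probe bias alone is argued against by the same genes on day 1, when their median was 0.53 (quartiles 0.06 and 1.22). A bias beside a real rise on day 1, when 8 of them were at least 2-fold higher, could give such a median and is not excluded. The separate scan of day 14 as the only cause is argued against by day 7, scanned with the other arrays, when their median was already -1.11 (quartiles -1.59 and -0.49). A session effect on the further step to -1.98 on day 14 is not excluded. An acute response of the sham muscle itself stays open, since no unoperated muscle was measured. The genes' median percentile of 97.2 in the sham channel of day 14 does not decide it, since picking genes below sham favours bright sham spots. Their sham level was much the same on day 1 (median difference, day 14 minus day 1, -0.09 on the log2 scale), when their median ratio was 0.53. High sham levels were thus not limited to the array used for picking. The level in undisturbed muscle remains unknown. A true deficit in the injured muscle therefore stays open too, as a hypothesis.

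Slow contractile genes stayed below sham on day 14 (7 of 12 at least 2-fold lower, none higher) while fast contractile genes lay above it (9 of 14 higher, none lower). A constant bias of the slow probes alone is argued against by the change of the slow minus fast difference by -2.28 between days 3 and 14. A bias beside a real change is not excluded. A smaller share of muscle RNA in the injured sample is argued against by the fast list's median of 1.23 (quartiles 0.25 and 1.61). That median was taken against the sham channel of day 14 alone. Against the mean of the 4 sham channels Myh2 was at 2.75, Pvalb at 1.65, Tnnt3 at 1.04 and Myh4 at 0.44, all smaller but still above 0. A different mix of fibres in the animals or muscle regions compared may be involved: sham channels themselves differed by up to 1.08 in the slow minus fast median between arrays, and the files do not say which animals they came from. A shift of regenerating fibres away from the slow program stays open and untested.

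Probes of the RT1 genes, the rat's major histocompatibility complex, did not all follow a common course. Of 39 measured on every array, 28 were at least 2-fold higher on day 7 and 23 on day 14, but 2 were at least 2-fold lower on day 14. RT1-Bb by its brighter probe was at -3.21, 0.35, 2.46 and -3.23 on days 1, 3, 7 and 14 and 1 of the 4 probes of RT1-Aw2 at -3.36, -0.02, 1.48 and -2.18, while the sham level of either probe varied by at most 0.57. A change of expression alone is argued against by probes of 1 gene that lay 5.32 apart on day 14, the 2 probes of RT1-Bb at -3.23 and 2.09. Sequence variants under the probes, carried by the outbred animals of days 1 and 14 and not by those of days 3 and 7 or the sham, may be involved: across 39 RT1 probes the differences day 1 minus day 3 and day 14 minus day 7, which share no array, correlated at 0.80 (0.52 by rank), above 99.98% of random probe sets. Without the 2 probes above the correlation was 0.53, at percentile 97.3 and short of the level set for this test, so the question stays open without genotypes.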

How the results depend on the processing

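Day counts and counts between days are given in order of time, and sham pairs as days 1 and 3, 1 and 7, 1 and 14, 3 and 7, 3 and 14, and 7 and 14. Leaving out time points for the genes past 2-fold on every day, naming genes by accession and symbol alone, and the mean of the 4 sham channels as control for named genes and lists, were chosen after the data were seen.

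No background correction, no filter on dim probes, the median of a gene's probes, the software's p-value under 0.01 and saturated spots left out kept every count they were run on within 1.5 times, as did random lists without matching the number of lists outside the range (22, 19, 20 and 22 against 21, 18, 18 and 21). Requiring both channels above background moved 2 of 22 counts, the sham pair of days 7 and 14 to 457 and the genes that rose in the mean to 0, and 14 of 132 list medians. Of the genes at least 2-fold from sham by the values reported, none was past 2-fold in the other direction under the processed signals, no background correction, an offset of 0 or median centring. Median centring kept all the higher genes past 2-fold but only 430 of 1127, 393 of 966, 76 of 289 and 97 of 371 lower genes, and the processed signals kept 283 of 285, 601 of 605, 677 of 734 and 745 of 748 higher and 1123, 963, 258 and 371 lower genes.

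The software's own processed signals gave 2753, 3758, 4058 and 4084 genes higher and 1958, 1814, 1892 and 1524 lower, 1944, 2821 and 2249 higher and 1213, 2348 and 2130 lower between days, 1245, 4536, 1106, 3027, 1930 and 4220 between sham channels, and 600 risen and 178 fallen in the mean. With them the miR-21 median was 0.28 and 0.32 on days 1 and 7. The deposited value table gave 2771, 3785, 4097 and 4101 higher and 1966, 1827, 1911 and 1534 lower, 1957, 2832 and 2259 higher and 1227, 2362 and 2141 lower between days, 600 risen and 178 fallen in the mean, and a miR-21 median of 0.28 and 0.32 on days 1 and 7. An offset of 0 gave 834, 1495, 1796 and 1685 higher, 619 and 833 lower on days 7 and 14, 1219, 1712 and 850 higher and 696, 941 and 702 lower between days, and 549, 2246, 398, 1345, 770 and 1644 between sham channels. An offset shrinks the ratios of dim spots by construction, and without it the counts between sham channels grew along with those of the injured muscle.

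Between 34.7% and 47.3% of the probes were well above background in the sham channel, which limits the folds of genes higher than sham, since a fold over a dimmer sham spot is a bound.

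Median centring leaves the dye trend with brightness in place. It moved all genes up by a median of 0.49, 0.39, 0.33 and 0.35, and gave 5003, 4198, 2722 and 2884 higher and 433, 395, 78 and 98 lower, 723 and 1033 lower from day 1 to 3 and from day 3 to 7, 81, 567, 55 and 435 for the first 4 sham pairs, 8398 risen and 132 fallen in the mean, and a miR-21 median of 0.79, 0.76, 0.55 and 0.53. The processed signals moved the median of all genes by 0.16 on day 7.

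The share of higher genes among those past 2-fold was 20.2%, 38.5%, 71.8% and 66.8% as reported, 58.4%, 67.4%, 68.2% and 72.8% with the processed signals, 58.5%, 67.4%, 68.2% and 72.8% with the deposited table, 33.5%, 51.0%, 74.4% and 66.9% with an offset of 0, 92.0%, 91.4%, 97.2% and 96.7% with median centring, and 33.1%, 46.5%, 54.0% and 66.0% against the mean of the 4 sham channels.

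Median centring also turned these medians from below 0 to above it: regenerating muscle to 0.34 on day 3, the neuromuscular junction to 0.19 on day 3, atrophy to 0.095, 0.28 and 0.23 on days 3, 7 and 14, neutrophils to 0.11 on day 3, monocytes and macrophages to 0.12 on day 14, interferon response to 0.27 on day 3, extracellular matrix to 0.46 on day 1. The others were proteases with 0.003 on day 14, the cell cycle with 0.02 on day 7, oxidative phosphorylation with 0.32 on day 1, the tricarboxylic acid cycle with 0.42 and 0.29 on days 1 and 3, glycolysis with 0.50 on day 7, fatty acid oxidation with 0.44 on day 7, heat shock with 0.26, 0.20 and 0.012 on days 3, 7 and 14. Among named genes it turned Serping1, Map2k3 and Ndufa5 on day 1 to 0.14, 0.17 and 0.11, and the ribosomal protein gene Rplp1 to 0.29 and 0.011 on days 3 and 7. No other alternative but the mean of the 4 sham channels, given below, changed the sign of a median outside its range or of a named gene past 2-fold, but many values moved: of 515 gene values and 136 list medians, the processed signals moved 360 and 48, the deposited ratios moved 355 and 47, an offset of 0 moved 309 and 25, median centring 506 and 101 beside those turned, the median of probes 112 and 3, and no background correction 31 and 0. The contractile, coupling, complement and lymphocyte lists kept their sign on every day they lay outside the range.

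A threshold of 3-fold gave 40, 122, 312 and 273 higher and 515, 431, 71 and 92 lower, and 243, 521 and 78 higher and 119, 126 and 72 lower between days. Direct comparison of the injured channels gave 604, 1224 and 490 lower between days and 1079 higher from day 7 to 14. The mean of the 4 sham channels as control gave 534 higher on day 1 and 718 lower on day 7. It turned Myod1 on day 7 to -0.54 and the median of oxidative phosphorylation on day 7 to -0.052, and brought 15 of 312 named values past 2-fold under it, Myh4 on day 14 to 0.44 among them. It moved 393 of 515 gene values and 8 of 136 list medians. Leaving out 1 time point gave 0 genes risen and 0 to 8 fallen in the mean, where 3 arrays leave fewer degrees of freedom, and 6 to 97 genes higher and 57 to 133 lower on every remaining day, the most higher without day 1 and the most lower without day 14. With genes named by accession and symbol alone the miR-21 median of day 1 was 0.27. Except where an alternative's construction is named above, the cause was not tested.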

Other observations

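Some lymphoid and red cell genes had unlike ratios on the single arrays of different days, which was not tested. The T cell receptor components Cd3d and Cd3g were at 0.09 and 0.09 on day 1 and at 2.65 and 3.44 on day 14, and the granule protein Nkg7 went from 0.28 to 1.90, while Cd8a was at -1.88 on day 14. The chemokine Cxcl9 was at 2.25 and Ccl5 at 3.58 on day 14. Of 39 probes of RT1 genes measured on every array 28 were at least 2-fold higher on day 7 and 23 on day 14, and Cd74, the invariant chain of class II molecules, was at -0.33, 0.02, 1.69 and 2.05 on days 1, 3, 7 and 14. The erythroid and platelet list lay at 0.01, 0.00, 0.52 and 0.28, above its range on day 7 with 4 of 9 genes higher. The globin gene Hbb-b1 was at 2.45 on day 7, with a saturated injured spot, and at 2.25 on day 14, and Alas2, of red cell heme synthesis, at 1.91 and 1.61, whereas the platelet factor Pf4 was at 1.07 on day 1 and -1.37 on day 14. These genes were chosen after their values were seen.

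Some fat and mast cell genes, chosen after their values were seen, also had unlike ratios on different days, which was not tested. Fat cell genes as a list were inside their range on days 1, 3 and 7. The adipocyte list lay at 0.33 on day 14, above its range, but at 0.21, inside it, with dim spots set to their bound, with the hormone Adipoq at 2.12, Retn at 2.09 (2.05 on day 3) and the desaturase Scd at 3.37 (4.88 on day 7), while the lipid droplet gene Plin1 was at 0.21 with a sham spot near background. Among mast cell genes the chymase Cma1 was at -1.80 on day 3 and 0.09 on day 14, and Cpa3 at -0.70 and 0.71. Of macrophage genes, Cd163 and Mrc1 were at -2.50 and -2.06 on day 14, while C1qa, Fcgr3a and Adgre1 were at 2.91, 2.48 and 0.98.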
